A study of Homo sapiens with 12 samples.

How the data were processed

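RNA from 12 samples of Caco-2 cells, a human colon adenocarcinoma line that takes on features of absorptive enterocytes once confluent, was measured on Agilent 2-colour oligonucleotide arrays. Per the labels, each array carried 1 sample in Cy5 and a pool of all RNAs of the study in Cy3, always in this dye orientation, so a dye effect is shared by all arrays and cancels in differences between groups. The design text calls the 3 samples of a group biological replicates. The labels describe 4 groups of 3 arrays, with replicates lettered a, b and c. DMEM-FBS was DMEM with 10% fetal bovine serum, and DMEM-Hemin the same medium with 100 µM hemin. SF-0 was serum-free, iron-free IMDM with a serum complement, and SF-FAC was SF-0 medium with 4.4 µM ferric ammonium citrate (FAC). The time of exposure is not given in the sources used here.

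The deposited table holds log10 ratios of sample over pool for 22153 probes, with 0 missing values. Spot intensities were not analysed here, so probes near background could not be filtered. The authors' scanner software and their within-array normalization are not given in the sources used here. The deposited log10 values were already centred: array medians, converted to log2, lay between -0.00455 and 0. No label gives the base of the logarithm, and the direction follows from the dyes in the labels. Both were checked against the pool. A pool of all samples makes the mean log ratio of a probe fall with its variance between groups, with a slope of -1.15 for base 10, -0.347 for base 2 and 1.15 for inverted ratios. The measured slope was -1.34 (SE 0.382) over 100 strongly varying probes. Because 528 probes hold a value of exactly 0 on at least 1 array and 25 on all 12, an exact 0 may stand for a spot without a measured ratio, and values are then given for each array.

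Probes were named from the platform annotation, updated through Entrez gene numbers in a RefSeq gene table. Of the 22153 probes, 18043 had 1 symbol, 17 had several and 4093 had none, and 18031 had a gene number found in that table, which changed 0 symbols. Log10 ratios were multiplied by 3.32 to give log2 ratios, each array was centred on its median, and probes of a gene with 1 symbol were averaged. Probes with no or several symbols stayed single features. This gave 19619 features, of which 15509 had 1 symbol. Control spots carry no mark in the values used here and may be among the unnamed features. Of 264 probes with a mean log10 ratio under -0.5, only 5 had 1 symbol. Whether the rest are control spots was not tested, and they were kept in the fit.

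Features were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group means only, all 12 arrays in 1 fit with 8 residual and 2.2 prior degrees of freedom). Calls were made at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The comparisons were DMEM-Hemin minus DMEM-FBS, SF-FAC minus SF-0, SF-0 minus DMEM-FBS, SF-FAC minus DMEM-FBS, the difference between the hemin and FAC effects, and a moderated F test over the 4 groups. Every adjusted p for a gene comes from this limma fit. The number of arrays limits the precision. The p-values measure the spread between these samples. Principal components were computed on the 15509 features with 1 symbol, and the positions of arrays on the axis from DMEM-FBS to SF-0 on those of them without an exact 0.

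Before the data were examined, 22 gene lists were written from textbook knowledge. They cover iron transport and storage, heme uptake, export and breakdown, heme synthesis, NRF2 targets, metallothioneins and zinc transport, hypoxia response (HIF) targets, cholesterol synthesis and uptake (SREBP2 targets), fatty acid synthesis, PPAR targets and fatty acid oxidation, cell cycle and DNA replication, immediate early and serum response genes, amino acid response and ER stress, heat shock response, p53 targets, NF-kappa B and inflammatory genes, iron-sulfur and mitochondrial iron proteins, enterocyte markers, goblet, Paneth and enteroendocrine markers, crypt and Wnt target genes, hepatocyte and fetal markers, fibroblast, endothelial and immune markers, and drug and steroid metabolism (AHR, PXR targets). Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists within each of 5 contrasts. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. Of the 27 calls of a list in a contrast, 1 held with an estimated correlation, that of the NRF2 targets with hemin. Fry called 12 of the 27 and 3 pairs that camera did not call. The median, mean and test direction differed in sign in 17 of the 110 pairs of list and contrast, 0 of them called.

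Genes were named by a rule also set before the data were examined. In the hemin, FAC and withdrawal comparisons it takes 8 iron and heme genes whatever their p (FTH1, among them, has no named probe and was not analysed here), the 10 largest called rises and 10 largest called falls whose groups do not overlap, and up to 2 called rises and 2 called falls of each list. It takes 5 each way in the other contrasts, and the 5 smallest p where fewer than 5 features passed. Genes outside the rule were chosen after their values were seen: those named from the fit without DMEM-FBS replicate a, where the 10 largest rises and falls were taken among features without an exact 0 and list members were picked from those called, and the list members whose call is given over the list alone.

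The fit was tested on simulated data with the residual spread of each of the 19619 features and 200 features changed by known folds, 50 at each fold. In the hemin comparison 20% of features changed 1.2-fold, 78% of those changed 1.5-fold, 88% of those changed 2-fold and 96% of those changed 3-fold were recovered, with 14 false calls. In the FAC comparison the shares were 14%, 74%, 84% and 94% with 6 false calls, and in the withdrawal comparison 22%, 74%, 88% and 96% with 8. Camera called both of 2 lists shifted by 0.2 (log2) and 0 of the others in each comparison. The simulated noise was set from the spread of single features, so it does not test camera on lists whose members vary together. In the real data the estimated correlation ranged from -0.0214 (fibroblast, endothelial and immune markers) to 0.469 (cholesterol synthesis and uptake).

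Alternatives were values without centring, quantile normalization, equal spread of the arrays, the replicate letter as a block, only the 6 arrays of a comparison, single probes, features with an exact 0 left out, the 25% of features with the smallest SD left out, robust eBayes, array weights, a minimum fold of 1.2, and each array left out in turn. Added after the data were seen were only features with 1 symbol, DMEM-FBS replicate a and exact zeros both left out, the block for gene lists, and the counts of list members and the largest changes without DMEM-FBS replicate a. Figures were drawn with matplotlib 3.10.9.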

Results

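Transcript levels were compared in fully differentiated Caco-2 cells kept in 4 media that differ in iron supply, with 3 arrays per group. The media were serum medium (DMEM-FBS), serum medium with 100 µM hemin, the ferric form of heme (DMEM-Hemin), iron- and serum-free medium (SF-0), and the latter with 4.4 µM ferric ammonium citrate, a non-heme iron salt (SF-FAC). Values are log2 ratios of each sample to a pool of all RNAs. Spearman correlations over all 22153 probes ranged from 0.63 to 0.83 between arrays of a group. Between arrays of different groups they ranged from 0.416 to 0.761. These ranges overlap, so a high value alone does not show agreement of replicates. The leading principal component, with 28.8% of the variance, placed the DMEM-Hemin arrays at 17.2 to 20.6 and the serum-free arrays at -15.6 to -7.91. DMEM-FBS replicates b and c lay at 6.72 and 8.97, while replicate a lay at -8.81, among the serum-free arrays. That array correlated with SF-0 replicates a and b at rho 0.733 and 0.718, with DMEM-FBS replicates b and c at 0.675 and 0.638, and with SF-0 replicate c at 0.628. SF-FAC replicates b and c also correlated better with an array of another group than with their own group. SF-FAC replicate c correlated with SF-0 replicate c at 0.761, against 0.704 and 0.678 with SF-FAC replicates a and b. Both of these groups are serum-free. SF-FAC replicate b correlated with DMEM-FBS replicate a at 0.7, against 0.63 and 0.678 with SF-FAC replicates a and c. That pair holds the same DMEM-FBS array again, so neither is a separate case of a serum array near serum-free ones. The moderated F test for any difference between the 4 groups called 1485 of 19619 features. That count was 137, 98 and 663 without DMEM-Hemin replicates a, b and c. It was 727 without SF-0 replicate b, 791 and 857 without SF-FAC replicates a and c, and 2780 with array weights.

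**Figure D1:**
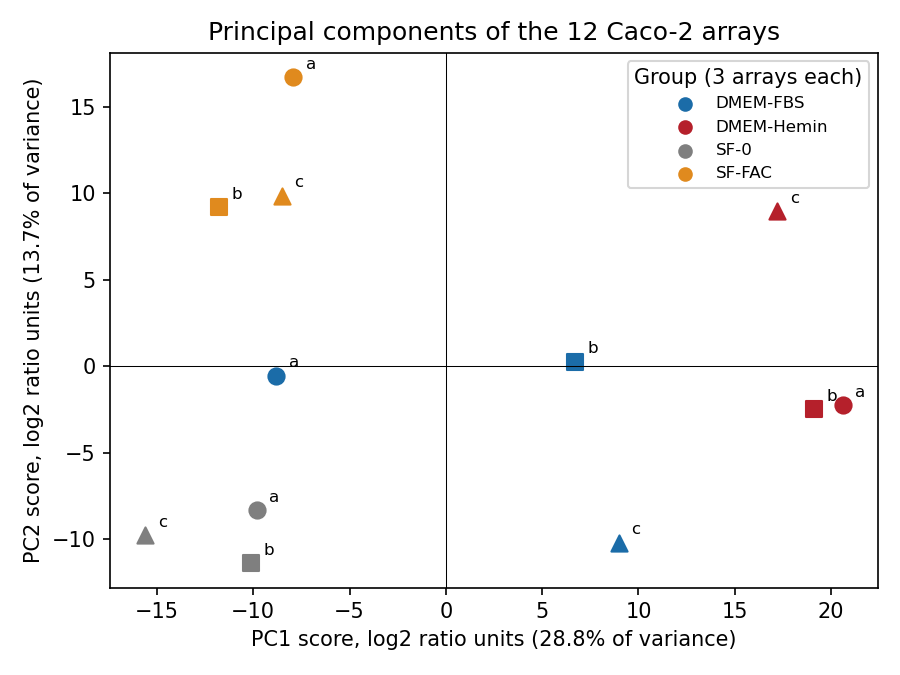
Scores of the 12 arrays on the 2 leading principal components of the log2 ratios (axes in log2 ratio units, with 28.8% and 13.7% of the variance), coloured by group, with replicate letters beside the points. DMEM-FBS replicate a, at -8.81 on the horizontal axis, lies on the side of the serum-free arrays, away from replicates b and c.

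The hemin comparison asks how hemin added to serum medium affects the cells. HMOX1, the heme oxygenase that breaks down heme, rose most, by 3.11 on the log2 scale (SE 0.50, 8.64-fold, n = 3 per group, adjusted p = 0.021), from a mean log2 ratio of -1.90 ± 0.82 (SD) to 1.21 ± 0.98. TFRC, the transferrin receptor of cellular iron uptake, fell 2.82-fold (log2 -1.50, SE 0.17, adjusted p = 0.0062), and FTL, the light chain of the iron store ferritin, rose 1.56-fold (log2 0.64, SE 0.099, adjusted p = 0.019). ALAS1, the rate-limiting enzyme of heme synthesis, fell 1.47-fold (log2 -0.55, SE 0.057, adjusted p = 0.0036), while ABCB6, a porphyrin transporter, rose 1.35-fold (adjusted p = 0.036). Other iron genes did not pass: the exporter ferroportin SLC40A1 had a log2 difference of -0.43 (adjusted p = 0.50), the ferrous iron importer SLC11A2 -0.23 (adjusted p = 0.15), the ferric reductase CYBRD1 -0.02 (adjusted p = 0.91) and the iron hormone HAMP -0.07 (adjusted p = 0.56). In total 344 features passed, 233 higher and 111 lower with hemin.

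Targets of NRF2, the transcription factor of the oxidative stress response, rose together: 11 of 39 measured members passed, all higher, and 21 were higher when adjusted over the list alone (camera adjusted p = 1.5e-14, and adjusted p = 0.0248 with an estimated correlation). They include GCLM, a subunit of the enzyme that starts glutathione synthesis (log2 1.07, SE 0.11, adjusted p = 0.0039), the quinone reductase NQO1 (0.82, SE 0.10, adjusted p = 0.0080) and the aldo-keto reductase AKR1C3 (1.19, SE 0.25, adjusted p = 0.049). HMOX1 and FTL belong to this list too. Metallothioneins, small metal-binding proteins, made up the 8 called members of a 13-gene list, all higher, and adjusted over the list alone 8 were higher and 1, the zinc transporter gene SLC30A2, lower (camera adjusted p = 3.95e-08, but adjusted p = 0.217 with an estimated correlation). MT1E rose 2.86-fold (log2 1.52, SE 0.13), MT2A 2.81-fold (1.49, SE 0.10), MT1G 2.52-fold and MT1B 2.33-fold. The 2 probes of MT1G gave 1.25 and 1.41, but those of MT1H gave 1.39 and 0.39 and those of MT1X 1.28 and 0.70. Metallothionein probes can cross-hybridise, so the single members are uncertain.

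Targets of the hypoxia-inducible factors lay lower with hemin in 30 of 34 cases (camera adjusted p = 9.75e-06, but adjusted p = 0.356 with an estimated correlation). Of these 34, 2 passed, DDIT4, an inhibitor of mTORC1 signalling (log2 -0.77, SE 0.097, adjusted p = 0.0088), and the glucose transporter gene SLC2A3 (-0.47, SE 0.094, adjusted p = 0.042). Adjusted over the list alone, 9 were lower and 1 higher. Part of this rests on DMEM-FBS replicate a, whose list mean was 0.188, against -0.057 and 0.018 on replicates b and c. Without that array the median log2 difference went from -0.168 to -0.095, and DDIT4 was the called member. Then 6 were lower and 0 higher over the list alone, and the list stayed called (camera adjusted p = 0.00038). The amino acid response and ER stress list was lower with 2 of 40 members called, DDIT4 and the secreted glycoprotein gene STC2, and 4 lower when adjusted over the list alone (camera adjusted p = 0.0143, adjusted p = 0.229 with an estimated correlation and 0.0811 without DMEM-FBS replicate b). Hepatocyte and fetal markers were higher, with 1 of 22 called, haptoglobin (HP, log2 0.63, SE 0.069, adjusted p = 0.0045), and 6 adjusted over the list alone (camera adjusted p = 0.00564, adjusted p = 0.47 with an estimated correlation and 0.0673 without DMEM-Hemin replicate a). The mean log2 ratio of this list was 0.31 and 0.18 on DMEM-Hemin replicates a and b but -0.14 on replicate c, below the -0.02 of DMEM-FBS replicate c. Drug and steroid metabolism genes were higher, with NQO1 and the sulfotransferase SULT2A1 called among 20 and 8 higher when adjusted over the list alone (camera adjusted p = 0.0221, adjusted p = 0.375 with an estimated correlation, 0.0934 without DMEM-FBS replicate b, and 0.0673 and 0.0968 without DMEM-Hemin replicates a and b).

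Immediate early and serum response genes were lower with 0 of 39 called, and 0 adjusted over the list alone (camera adjusted p = 0.00987, adjusted p = 0.47 with an estimated correlation and 0.109 without DMEM-FBS replicate a). Crypt and Wnt target genes were higher as a list although their called member, the secreted matrix protein gene SMOC2, fell (log2 -0.75, SE 0.11). Adjusted over the list alone, 2 of its 19 members were higher and 1 lower (camera adjusted p = 0.0497, adjusted p = 0.229 with an estimated correlation, 0.0502 without centring and 0.0721 under quantile normalization). The adjusted p of this list was 0.113 without DMEM-FBS replicate b, 0.0673 and 0.12 without DMEM-Hemin replicates a and b, and 0.0508, 0.0622 and 0.0631 without SF-0 replicates a, b and c. It was 0.0598, 0.0567 and 0.0554 without SF-FAC replicates a, b and c. In lists that were not called, the malic enzyme ME1 was the 1 of 19 fatty acid synthesis genes to pass (log2 0.48, SE 0.074), the replication factor GINS2 the 1 of 52 cell cycle genes (0.43, SE 0.073), and TXNIP, the thioredoxin-interacting protein, the 1 of 27 PPAR targets (-0.85, SE 0.13).

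Among the other large rises were the glutathione transferase GSTA3 (log2 1.17, SE 0.24), the transcription factor SOX11 (1.10, SE 0.14) and the deubiquitinating enzyme UCHL1 (1.02, SE 0.20). The large falls included the lipid droplet protein HILPDA (-1.09, SE 0.22), BEND7 (-1.06, SE 0.19), the epithelial sodium channel subunit SCNN1A (-1.02, SE 0.21), the polyamine acetyltransferase SAT1 (-0.97, SE 0.20), TMEM140 (-0.93, SE 0.16), the ephrin EFNA1 (-0.78, SE 0.16) and the secreted protease HTRA1 (-0.78, SE 0.094). Of the 31 called genes named for hemin, 12 passed in each of the 12 fits with 1 array left out: TFRC, MT1E, MT2A, MT1G, MT1B, SOX11, GCLM, NQO1, HP, ALAS1, DDIT4 and HTRA1. HMOX1 missed the threshold without DMEM-FBS replicate a or without DMEM-Hemin replicate a (adjusted p = 0.065 in both), and FTL without DMEM-FBS replicate b or without DMEM-Hemin replicate a, b or c (0.059, 0.073, 0.06 and 0.063). The other 17 missed it in at least 1 of these fits, with adjusted p up to 0.15, SLC2A3 in each of them. Fitted on the 6 arrays of the comparison alone, 25 of the 31 did not pass, with adjusted p of 0.12 for HMOX1, 0.085 for TFRC and 0.098 for FTL. The count of 344 was 92 and 72 without DMEM-FBS replicates a and b, 60, 45 and 91 without DMEM-Hemin replicates a, b and c, 187 and 172 without SF-0 replicates a and b, and 199 without SF-FAC replicate a. It lay between 10 (minimum fold of 1.2) and 609 (array weights) over all alternatives.

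**Figure D2:**
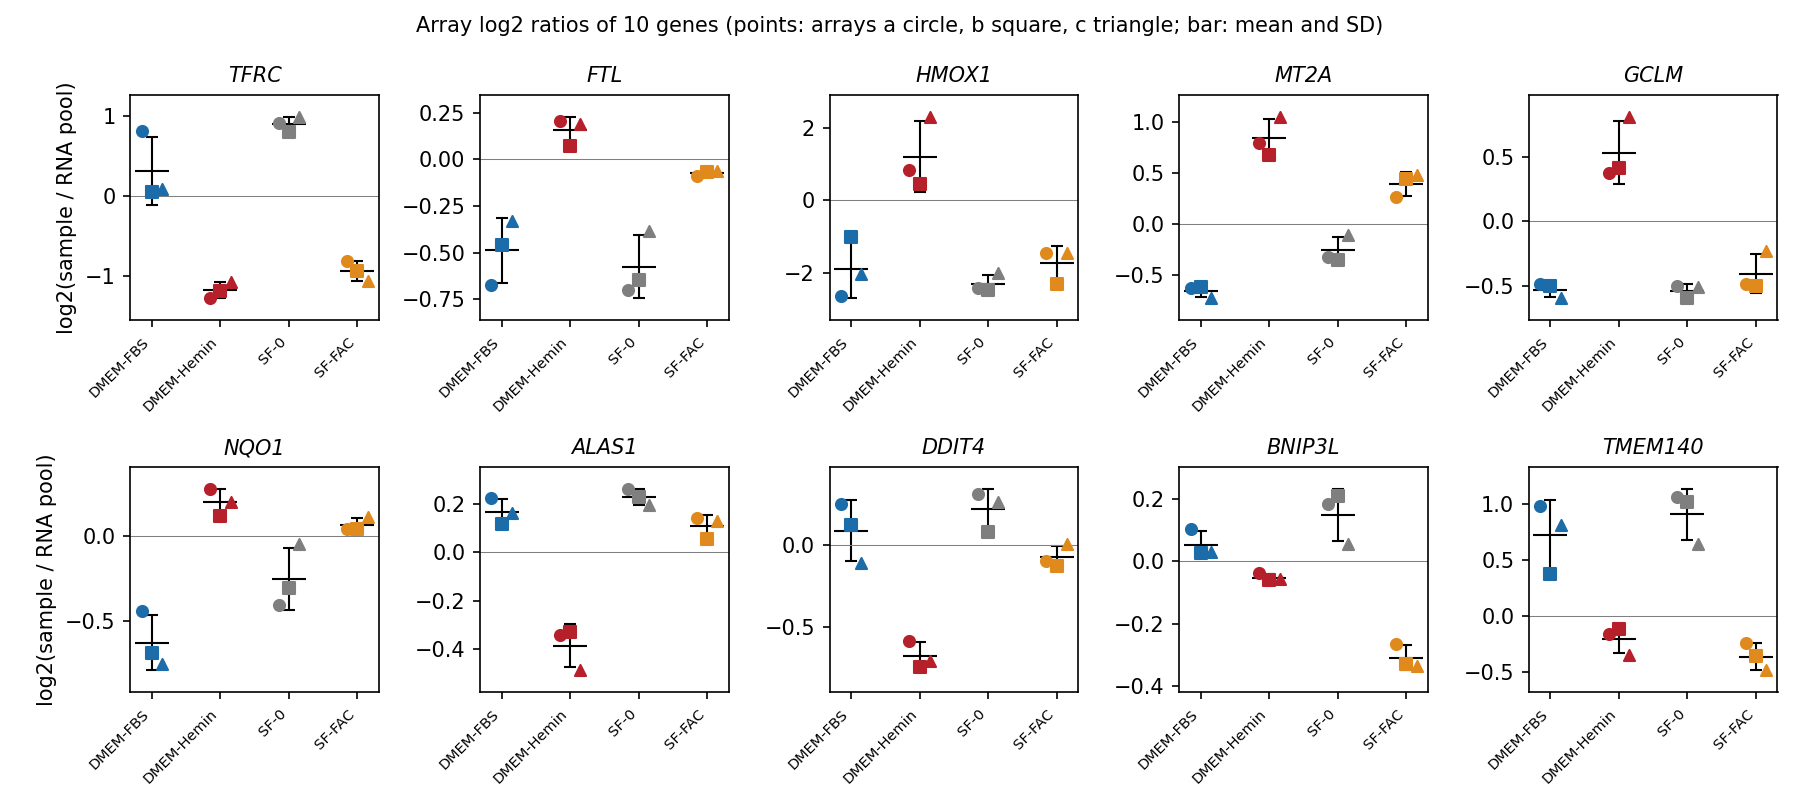
Log2 ratio of sample to RNA pool (vertical axes, a separate scale for each gene) of 10 genes on each of the 12 arrays, by group (horizontal axes); symbols mark replicates a, b and c, and bars give the mean and SD of 3 arrays. TFRC lies between -1.27 and -0.80 on the DMEM-Hemin and SF-FAC arrays and at 0.81 to 0.99 on the SF-0 arrays and DMEM-FBS replicate a, while HMOX1 is above 0 on the DMEM-Hemin arrays only.

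The FAC comparison asks what iron salt alone changes in serum-free medium. TFRC fell 3.57-fold (log2 -1.83, SE 0.17, n = 3 per group, adjusted p = 0.0050), from a mean log2 ratio of 0.90 ± 0.092 (SD) in SF-0 to -0.93. The metallothioneins MT1E (log2 1.04, SE 0.13, adjusted p = 0.026), MT1G (0.81, SE 0.11), MT1H (0.74, SE 0.095) and MT1X (0.66, SE 0.093) rose, as did CRIP1, a small LIM domain protein of the intestine (0.82, SE 0.12), and the ATP synthase subunit ATP5PF (0.51, SE 0.072). TMEM140 (-1.27, SE 0.16), the guanine nucleotide exchange factor ARHGEF16 (-0.58, SE 0.066), FAM156A (-0.50, SE 0.065), the mitophagy receptor BNIP3L (-0.46, SE 0.053) and the interferon-induced IFIT1 (-0.39, SE 0.052) fell. FTL had a log2 difference of 0.50 that did not pass (SE 0.099, adjusted p = 0.087), and neither did HMOX1 at 0.57 (SE 0.50, adjusted p = 0.62), SLC40A1 at -0.58 (adjusted p = 0.38), SLC11A2 at -0.03 (adjusted p = 0.87), CYBRD1 at -0.07 (adjusted p = 0.53) or HAMP at -0.12 (adjusted p = 0.34).

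Of the 16 features called with FAC, 9 were higher and 7 lower, against 4 and 5 under quantile normalization and 13 and 23 with equal spread of the arrays. Among the 16, ROR1, MAGEB3 and AKAP4 are listed at exactly 0 on many arrays. ROR1, a receptor-like kinase gene, had log2 ratios of -2.08, -2.39 and -1.80 in SF-0 and of 0, 0 and -0.18 in SF-FAC. MAGEB3 had 0.07, 0 and 0 in SF-0 and 1.21, 0.91 and 1.05 in SF-FAC. AKAP4 had 0.90, 0.55 and 0.77 in SF-0 and 0 on the 3 SF-FAC arrays. Without SF-FAC replicate c, TFRC missed the threshold (log2 -1.77, adjusted p = 0.051) and 2 features were called, against 43 without DMEM-FBS replicate a, 7 without DMEM-FBS replicate c or SF-0 replicate b, and 6 without SF-FAC replicate b. Of the 15 called genes named for FAC, ROR1 and MAGEB3 passed in each of the 12 fits with 1 array left out. MT1E passed in 6 of them, with its highest adjusted p, 0.11, without SF-0 replicate b. The other 11 missed it in at least 1 of these fits, with adjusted p up to 0.12 for CRIP1, MT1X and ATP5PF, again without SF-0 replicate b. Under quantile normalization MT1H kept its call among the metallothioneins, while MT1E (adjusted p = 0.063), MT1G and MT1X (0.061 each) lost it with the same direction, as did TMEM140, CRIP1, ATP5PF and IFIT1 (0.061 each). Over all alternatives the count of 16 lay between 2 and 78, the latter with array weights. Fitted on the 6 arrays of the comparison alone, 10 of the 15 did not pass, with adjusted p of 0.13 for BNIP3L, 0.11 for MT1X, 0.051 for MT1G and TMEM140, 0.19 for CRIP1 and 0.2 for ATP5PF.

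The hypoxia response list lay lower with FAC in 33 of 34 members (median log2 -0.29, camera adjusted p = 7.79e-13, but adjusted p = 0.164 with an estimated correlation). BNIP3L was its called member, and 15 were lower when adjusted over the list alone, among them the glycolytic enzyme PGK1 (log2 -0.57, SE 0.12) and the HIF prolyl hydroxylase EGLN1 (-0.43, SE 0.078). Of the 13 genes for metallothioneins and zinc transport, 4 were called higher, and 8 were higher and 1, the zinc transporter gene SLC39A10, lower when adjusted over the list alone (camera adjusted p = 3.74e-09, but adjusted p = 0.164 with an estimated correlation). Iron-sulfur and mitochondrial iron proteins were higher in 29 of 35 members, with 0 called and 3 adjusted over the list alone: NDUFS7, NFU1 and PPAT (camera adjusted p = 0.000107, adjusted p = 0.267 with an estimated correlation). Cholesterol synthesis and uptake genes were lower in 19 of 21, with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.00048, adjusted p = 0.486 with an estimated correlation).

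NRF2 targets were higher with FAC by a median of 0.11, with 0 of 39 called and 1 adjusted over the list alone (camera adjusted p = 0.0125, adjusted p = 0.385 with an estimated correlation, 0.128 under quantile normalization, and 0.0628 and 0.056 without SF-0 and SF-FAC replicate c). Immediate early and serum response genes and NF-kappa B and inflammatory genes were lower, each with 0 members called, 0 adjusted over the list alone and a camera adjusted p of 0.0484. With an estimated correlation their adjusted p were 0.661 and 0.267. Both lists had an adjusted p of 0.0508 without centring, 0.0517 without DMEM-FBS replicate c, and 0.0613 and 0.0524 without DMEM-Hemin replicates a and b, and of 0.0787 and 0.0915 under quantile normalization. Immediate early genes also missed the threshold without SF-0 replicate a (0.116) and SF-FAC replicates a and c (0.132 and 0.364), and NF-kappa B genes without SF-0 replicate c (0.177) and SF-FAC replicates a and c (0.0739 and 0.124). In the iron transport and storage list TFRC was called, and FTL was higher when adjusted over the list alone (camera adjusted p = 0.12).

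**Figure D3:**
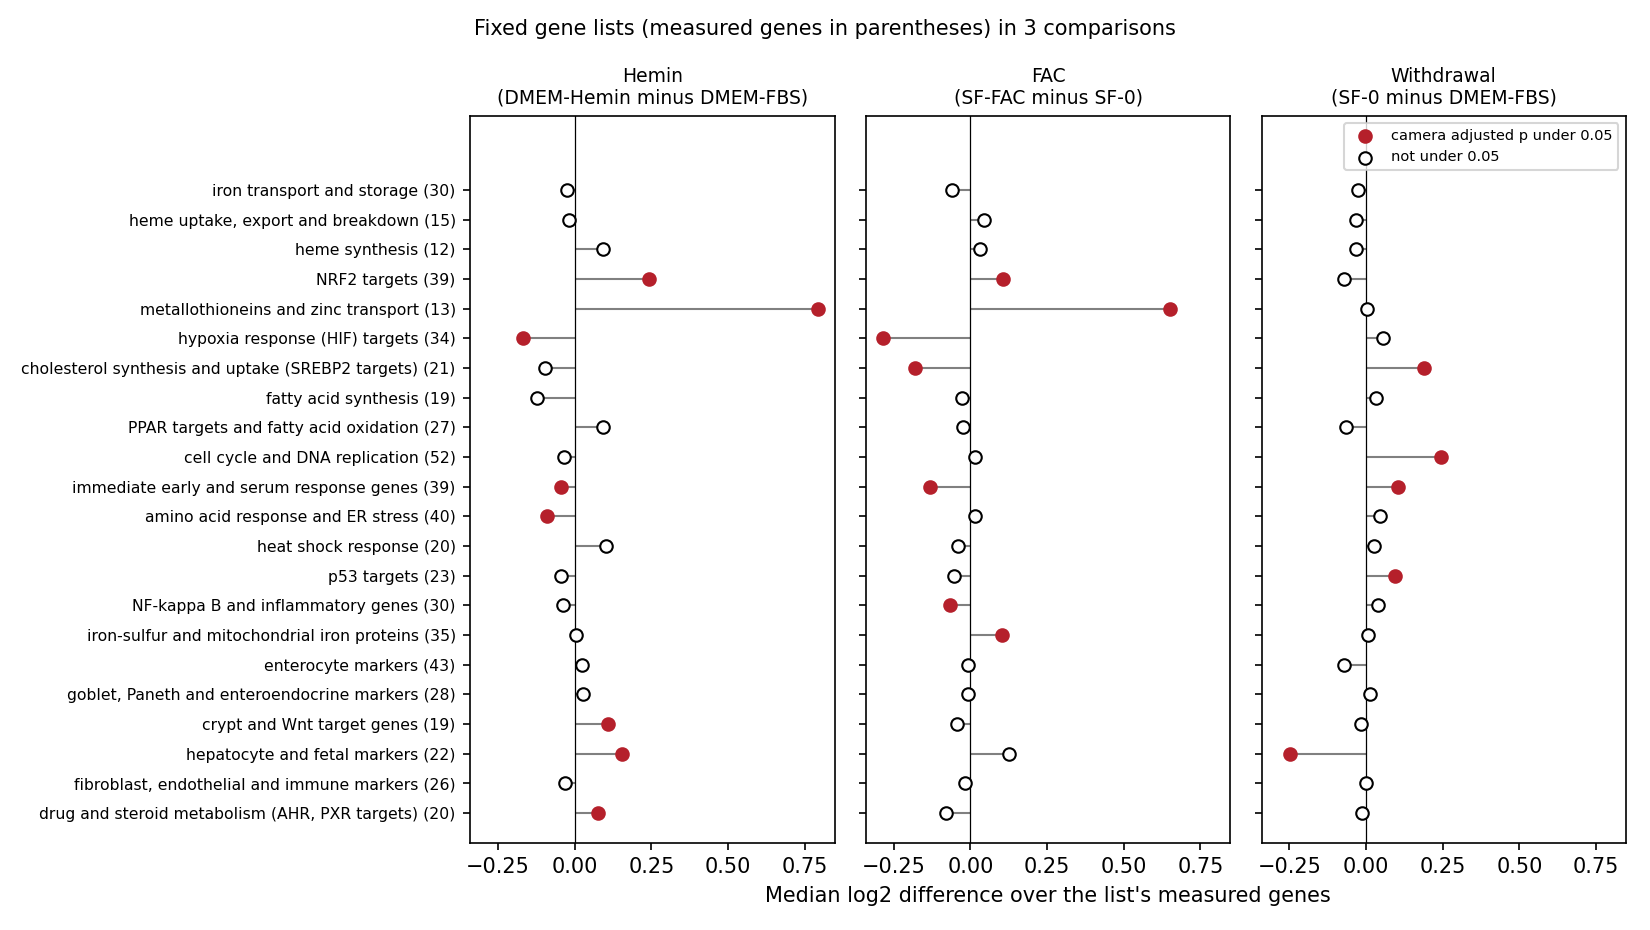
Median log2 difference over the measured members of each of the 22 gene lists (horizontal axis) in the hemin, FAC and withdrawal comparisons, with filled points where the camera adjusted p was under 0.05. Metallothioneins lie at 0.79 with hemin and 0.65 with FAC, and the hypoxia response list at -0.17 and -0.29, while only the NRF2 list with hemin was also called with an estimated correlation.

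The withdrawal comparison sets iron- and serum-free IMDM against serum-containing DMEM, so basal medium, serum and iron change together. With all 12 arrays, 2 of 19619 features passed, ROR1 (lower in SF-0) and AKAP4 (higher), and both are listed at exactly 0 on DMEM-FBS replicates a and b. With features holding an exact 0 left out, limma called 0, and 3089 features had an unadjusted p under 0.05 with all features kept. The split was 0 higher and 1 lower under quantile normalization. The count was 1 without DMEM-FBS replicate b or c, DMEM-Hemin replicate c, or SF-FAC replicate b or c, 28 and 5 without SF-0 replicates a and b, and 631 without DMEM-FBS replicate a. TFRC had a log2 difference of 0.58 that did not pass (SE 0.17, adjusted p = 0.18). The smallest p after ROR1 and AKAP4 belonged to AP3S2 (-1.45, adjusted p = 0.081), NFIX (-1.08, adjusted p = 0.098) and CXorf38 (0.64, adjusted p = 0.084), which did not pass. Nor did FTL (-0.09, adjusted p = 0.70), HMOX1 (-0.41, adjusted p = 0.73), SLC40A1 (-0.46, adjusted p = 0.47), SLC11A2 (-0.19, adjusted p = 0.26), CYBRD1 (0.04, adjusted p = 0.75) or HAMP (-0.03, adjusted p = 0.85).

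As groups, cell cycle and DNA replication genes were higher in SF-0 in 49 of 52 members, with 0 called and 14 adjusted over the list alone, led by the ribonucleotide reductase subunit RRM2 (log2 0.65, SE 0.14). The camera adjusted p was 2.68e-12, but adjusted p = 0.631 with an estimated correlation. Cholesterol synthesis and uptake genes were higher in 17 of 21 (camera adjusted p = 0.00145, but adjusted p = 0.631 with an estimated correlation) and immediate early and serum response genes in 30 of 39 (camera adjusted p = 0.00151, and again 0.631 with an estimated correlation). In both, 0 members were called over all features or adjusted over the list alone. Both had an adjusted p = 0.0582 without DMEM-FBS replicate c. The p53 targets were higher, with 0 called, and 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0472, adjusted p = 0.631 with an estimated correlation). Their adjusted p was 0.0511 under quantile normalization, 0.0761 and 0.21 without DMEM-FBS replicates b and c, and 0.0587 and 0.0532 without DMEM-Hemin replicates a and c. It was 0.125 without SF-0 replicate c, and 0.0596 and 0.0565 without SF-FAC replicates a and c. Hepatocyte and fetal markers were lower in 20 of 22, with 0 called and 1 adjusted over the list alone (camera adjusted p = 0.00151, adjusted p = 0.631 with an estimated correlation, 0.0582 without DMEM-FBS replicate c and 0.125 without SF-0 replicate c).

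The number of genes called here depended on DMEM-FBS replicate a. Without it, a fit planned in advance and described in detail after the data were seen, 631 features passed, 369 higher and 262 lower in SF-0, with 2 arrays left in the serum group. Since replicate a lay towards SF-0, leaving it out widens the difference and narrows the spread within DMEM-FBS. If that array is a valid serum sample, the counts and adjusted p of this fit overstate the change. TFRC rose 1.78-fold in this fit (log2 0.83, SE 0.090, adjusted p = 0.0024), and its log2 ratio was 0.81 on replicate a, against 0.06 and 0.09 on replicates b and c. The cell cycle list had 21 of 52 members called, all higher, such as RRM2 (0.85, SE 0.071) and the DNA topoisomerase TOP2A (0.70, SE 0.088), and 30 adjusted over the list alone. Of 21 cholesterol synthesis and uptake genes 8 rose, among them INSIG1 (0.83, SE 0.070) and ACAT2 (0.91, SE 0.11), and 13 were higher adjusted over the list alone. Of 39 immediate early and serum response genes 8 rose, led by EGR1 (2.39, SE 0.24), and 15 were higher adjusted over the list alone. EGR1 stood at 1.00 on DMEM-FBS replicate a, at -1.62 and -1.75 on replicates b and c, and at a mean of 0.71 in SF-0. AP3S2, NFIX and CXorf38, picked with replicate a included, kept it with its group, at log2 ratios of 1.06, -0.15 and 0.12 against means of -0.34, -1.34 and 0.60 in SF-0.

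The other large rises in the fit without that array were CEACAM6, a cell adhesion glycoprotein (log2 2.24, SE 0.21), TP53I3, IGFBP7, ISG20, the matrix metalloproteinase MMP7 (1.48, SE 0.13), PTH1R, NPTX1, B3GNT3 and DUSP6. The falls were led by G0S2, an inhibitor of triglyceride lipase (-2.04, SE 0.30), AKR1C1 (-1.62, SE 0.19), LGALS2, AP3S2 and RBP2, the retinol-binding protein of enterocytes (-1.41, SE 0.19), with MIP, RHOBTB1, CATSPER3, TBX2 and AKR1C3. The adjusted p of these 20 genes, EGR1 included, was at most 0.035. With all arrays it lay between 0.081 and 0.34, so they did not pass. The omitted array stood at 0.95 for CEACAM6, 0.94 for TP53I3, -1.81 for AKR1C1 and -1.18 for TBX2. The SF-0 means of these genes were 0.37, 0.60, -1.91 and -1.06, so on them that serum sample showed little or no difference from SF-0. For MIP and AP3S2 it stood at -0.20 and 1.06, against SF-0 means of -1.23 and -0.34. Of 43 enterocyte markers, 2 fell in the fit without it, the lipoprotein assembly factor MTTP (-1.01, SE 0.20) and the triglyceride synthase DGAT1 (-0.61, SE 0.11). Adjusted over the list alone, 6 were lower and 2 higher. With all arrays the adjusted p of MTTP and DGAT1 were 0.19 and 0.21.

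SF-FAC against DMEM-FBS is a secondary comparison in which medium, serum and iron form all differ. MT2A rose 2.07-fold (log2 1.05, SE 0.10, adjusted p = 0.010), followed by MT1E (0.99, SE 0.13), CRIP1 (0.92, SE 0.12) and MT1G (0.89, SE 0.11). TFRC fell 2.38-fold (-1.25, SE 0.17, adjusted p = 0.046), as did the receptor GPR146 (-1.17, SE 0.12), TMEM140 (-1.09, SE 0.16), ARHGEF16 (-0.46, SE 0.066) and BNIP3L (-0.36, SE 0.053). MAGEB3, listed at 0 on the DMEM-FBS arrays, was called too. With 1 array left out, MAGEB3 passed in each of the 12 fits, and the other 9 missed the threshold in at least 1. MT2A and GPR146 passed in 8 (adjusted p up to 0.084, without DMEM-FBS replicate c) and TFRC in 2 (up to 0.19, without SF-FAC replicate c). Fitted on the 6 arrays of the comparison alone, each of the 10 missed the threshold, with adjusted p of 0.21 for TFRC and 0.098 for MT2A. In all 18 features passed, 13 higher and 5 lower, against 64 and 56 with equal spread of the arrays and 57 and 31 under quantile normalization. Without DMEM-FBS replicate a 544 passed, and 42 without SF-0 replicate c. The count was 1 without DMEM-FBS replicate b or c or SF-FAC replicate b or c, 3 without DMEM-Hemin replicate a or SF-0 replicate a or b, 8 and 11 without DMEM-Hemin replicates b and c, and 9 without SF-FAC replicate a.

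Cell cycle genes were higher in SF-FAC than in DMEM-FBS in 48 of 52 members, with 0 called and 25 adjusted over the list alone (camera adjusted p = 4.13e-15, but adjusted p = 0.26 with an estimated correlation). Metallothioneins and zinc transport genes were higher, with 6 of 13 called and 7 adjusted over the list alone, and the hypoxia response list was lower, with BNIP3L called among 34 and 11 adjusted over the list alone. Their camera adjusted p were 1.21e-08 and 3.2e-09, and each had an adjusted p = 0.231 with an estimated correlation. Iron-sulfur and mitochondrial iron proteins were higher with 0 of 35 called, and 0 adjusted over the list alone (camera adjusted p = 0.000342, adjusted p = 0.26 with an estimated correlation). Hepatocyte and fetal markers were lower with 0 of 22 called and 1 adjusted over the list alone (camera adjusted p = 0.0264, adjusted p = 0.767 with an estimated correlation, 0.326 without DMEM-FBS replicate c, and 0.173 and 0.237 without SF-FAC replicates b and c).

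The hemin and FAC effects were tested against each other, although dose, iron form and medium differ between them. HTRA1 fell with hemin but had a log2 difference of 0.27 with FAC, a difference of effects of -1.05 (SE 0.13, adjusted p = 0.039). The nucleotide receptor P2RY6 (0.83, SE 0.10, adjusted p = 0.037) and TOMM40L, a relative of the mitochondrial import channel (0.68, SE 0.072, adjusted p = 0.020), differed the other way, with values of 0.58 and 0.51 for hemin and -0.25 and -0.17 for FAC. With 1 array left out, HTRA1 passed in 4, P2RY6 in 3 and TOMM40L in 6 of 12 fits. Their adjusted p reached 0.11 for HTRA1 and P2RY6 without DMEM-Hemin replicate a and 0.081 for TOMM40L without DMEM-FBS replicate b. In all 6 features passed, 2 higher and 4 lower, against 24 and 15 under quantile normalization and 74 and 31 with equal spread of the arrays. NRF2 targets responded more to hemin, with 0 of 39 called and 10 adjusted over the list alone (camera adjusted p = 5.51e-05, adjusted p = 0.225 with an estimated correlation). Drug and steroid metabolism genes differed the same way, but their median was 0.08 with hemin and -0.08 with FAC. With FAC 0 were higher and 3 lower over the list alone, and the list was not called (camera adjusted p = 0.111). For the difference, 0 of 20 were called and 7 adjusted over the list alone, such as the glutathione transferase GSTA1 (difference 2.03, SE 0.45). Its camera adjusted p was 0.004 for this list, and the adjusted p was 0.335 with an estimated correlation. Without DMEM-FBS replicate b, DMEM-Hemin replicate c or SF-FAC replicate a, 0 features passed in limma, with 3558 at an unadjusted p under 0.05 when all arrays are kept. The count was 38 without SF-0 replicate c, 14 and 12 without SF-0 replicate b and SF-FAC replicate c, and 10 without DMEM-FBS replicate a. It was 3 without SF-FAC replicate b, 2 without DMEM-Hemin replicate b, and 1 without DMEM-FBS replicate c or DMEM-Hemin replicate a.

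Across 19619 features the hemin and FAC effects, which share no array, were almost uncorrelated (Pearson's r 0.0352, Spearman's rho -0.0282, across genes, which are not independent replicates). Most features were called in neither comparison, so noise pulls this correlation towards 0. It does not show that the 2 iron sources act differently. The Pearson correlation was -0.0248 without DMEM-Hemin replicate c and -0.000826 without SF-FAC replicate c. MT1E, MT1G, MT1H and MT1X were called higher in both, 4 features where independent lists would share 0.11. TFRC and TMEM140 were called lower in both, 2 where independent lists would share 0.04. The 4 metallothioneins correlated with MT2A over all arrays at 0.953, 0.979, 0.955 and 0.977, and cross-hybridisation stays open. They may thus be a single signal counted 4 times, so setting 4 against 0.11 may overstate the overlap. Under quantile normalization MT1E, MT1G, MT1X and TMEM140 lost their FAC call, which takes 4 of the 6 shared features out of the overlap. Their log2 differences were then 1.03, 0.81, 0.67 and -1.28, against 1.04, 0.81, 0.66 and -1.27 in the main fit. Of the 233 features higher with hemin 56.2% had a positive FAC value, against 48.2% of all features, and of the 111 lower ones 57.7% had a negative value, against 51.8%.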

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

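The counts of splits in this part were chosen after the results were seen. The features and lists below differed between the hemin and FAC effects by the test of that difference. TOMM40L (difference of log2 effects 0.68), P2RY6 (0.83) and HTRA1 (-1.05) have 1 named probe each with no value of exactly 0. Probe 15255, which has no symbol here, had a difference of -0.80, with -0.26 for hemin and 0.54 for FAC. MAGEB3 (-0.98) and ROR1 (-1.79) are listed at exactly 0 on most arrays outside SF-FAC and SF-0, respectively, and their values rest on the 3 arrays of that group. Each of these 5 named genes missed the threshold in at least 1 of the 12 fits with 1 array left out. The NRF2 targets had a median difference of 0.17 and the drug and steroid metabolism genes one of 0.36, but with an estimated correlation their adjusted p were 0.225 and 0.335.

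For the difference of effects, 4 of 100 splits of the 12 arrays gave 6 or more features, the real one included, and the highest of the others called 346. That split set DMEM-FBS replicate b and DMEM-Hemin replicates b and c against DMEM-FBS replicate a and SF-0 replicates a and c, so it mixes effects of the media into the difference. Such splits are no test of a difference between effects, and chance stays open for the 6 features. For the F test, 1 of 100 splits, the real one with 1485 features, gave as many, and the highest of the others was 100. Chance is thus unlikely as the source of that count, but 100 splits cannot exclude it, and single features are not covered.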

How the results depend on the processing

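Features with 1 symbol, the joint removal of DMEM-FBS replicate a and exact zeros, the block for gene lists, and the list members and largest changes without DMEM-FBS replicate a were chosen after seeing the data. The requirement of at least 2 values per group changes nothing, since 0 values are missing, and was not run. Over the alternatives, 2048 values of named genes were recomputed: 1559 kept their side of the threshold, 476 fell short of it and 13 newly passed. Of the called ones 0 changed direction. Values near 0 that were not called changed sign for CYBRD1 with hemin (2 of 24 settings) and SLC11A2 with FAC (2 of 25). HMOX1 in withdrawal, also not called, changed sign in 1 of 25, from -0.41 with all arrays to 0.03 with 1 array left out. Of 459 list values 363 kept their call and 96 lost it. The cause was not tested unless stated. Counts are given in the order hemin, FAC, withdrawal, SF-FAC against DMEM-FBS and difference of effects, against 344, 16, 2, 18 and 6. Quantile normalization moved the last 4 to 9, 1, 88 and 39, and equal spread of the arrays to 36, 4, 120 and 105. Array weights gave 609 for hemin, 78 for FAC, 146 for SF-FAC against DMEM-FBS, 194 for the difference and 2780 for the F test. A minimum fold of 1.2, a stricter test by construction, gave 10, 3, 1, 1 and 0. Leaving out the 25% of features with the smallest SD gave 212, 34 and 5 for the first 3. Only the 6 arrays of a comparison, which leave fewer degrees of freedom, gave 32 for hemin, 18 for FAC (10 of its 15 named genes lost) and 0 for withdrawal and for SF-FAC against DMEM-FBS. Single probes gave 47 for FAC and 9 for withdrawal, and features without an exact 0 gave 0 for withdrawal. Features with 1 symbol gave 438 for hemin, 29 for FAC and 18 for the difference. Without DMEM-FBS replicate a and exact zeros the first 4 counts were 97, 51, 662 and 564. With 1 array left out, counts ranged from 45 to 360 for hemin, 2 to 43 for FAC, 1 to 631 for withdrawal, 1 to 544 for SF-FAC against DMEM-FBS, 0 to 38 for the difference and 98 to 2148 for the F test, where a group left with 2 arrays shares the spread of the others. The highest values for FAC, withdrawal, SF-FAC against DMEM-FBS and F arose without DMEM-FBS replicate a. List calls numbered 27, 21 to 35 with 1 array left out, and 1 held with an estimated correlation. Fry called 12 of the 27 and 3 others. The correlation of hemin and FAC effects ranged from -0.0248 to 0.0956 with 1 array left out, and turned negative without DMEM-Hemin replicate c (-0.0248) and SF-FAC replicate c (-0.000826). The letters a, b and c were not taken to pair the samples. The criterion used here was that every same-letter pair of residuals correlates above 0.1. These correlations ranged from -0.126 to 0.148, with a mean of 0.029, against -0.015 for pairs with other letters. Of 18 same-letter pairs 5 exceeded 0.1, as did 1 of 36 pairs with other letters. Of 12 arrays, 6 correlated best with their own letter. A weaker effect shared by arrays of a letter thus stays open. With the replicate letter as a block the counts were 243, 14, 8, 6 and 3, and 25 list calls were made. The 5 named genes of the difference then had adjusted p of 0.061 to 0.079. For hemin 7 of 31 named genes lost their call: AKR1C3, GSTA3, SULT2A1, ABCB6, SAT1, SCNN1A and BEND7 (adjusted p 0.052 to 0.081). For FAC 5 of 15 did: MT1G, MT1H, MT1X, IFIT1 and FAM156A (0.052 to 0.059). For SF-FAC against DMEM-FBS 5 of 10 did. Without intensities, dim probes could not be told from bright ones, which limits every value near the pool's level.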

Other observations

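The tests chosen only after the result was seen were the counts of splits, the test of DMEM-FBS replicate a on features with large differences, the scaling tests of both lists, the test of SLC30A1 and that of the estimated correlation of the hypoxia list. Those on array positions, on the noise of DMEM-FBS replicate a, on correlations with MT2A and on the correlation of list members were set before their result was seen. With FAC, several list members with large differences passed only when adjusted over the list alone, and they were chosen here after their values were seen. TP53I3, a p53 target, had a log2 difference of -2.37 (SE 0.51, adjusted p = 0.109 over all features), the fibrinogen chain FGG -1.36 (SE 0.28, adjusted p = 0.0974), the brush border peptidase DPP4 -1.09 (SE 0.25, adjusted p = 0.119) and BACH1, a heme-binding transcriptional repressor, -0.35 (SE 0.063, adjusted p = 0.077). The hypoxia list with hemin held P4HA2 (-0.72, SE 0.21, adjusted p = 0.112), VEGFA (-0.39, SE 0.086, adjusted p = 0.055) and, in the other direction, TPI1 (0.31, SE 0.087, adjusted p = 0.104) on the same terms. In the heme lists with hemin, FECH, which inserts iron into porphyrin, had 0.22 (SE 0.054, adjusted p = 0.0712) and FLVCR2 0.23 (SE 0.062, adjusted p = 0.1).

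Of the 22 lists, camera called 9 in 0 of the 5 contrasts. Fry called 2 of these 9, iron transport and storage lower in SF-FAC than in DMEM-FBS (adjusted p = 0.018) and the heat shock response higher with hemin (0.0444). It also called crypt and Wnt target genes higher in the difference of effects (0.0179), where camera did not. The lowest camera adjusted p was 0.0525 for both iron transport and storage and enterocyte markers, each lower in SF-FAC than in DMEM-FBS. It was 0.0902 for heme synthesis, 0.179 for fatty acid synthesis, 0.197 for heme uptake, export and breakdown and 0.26 for the heat shock response, all with hemin, and 0.1 for PPAR targets and fatty acid oxidation in the withdrawal comparison. For markers of other cell types it was 0.354 for goblet, Paneth and enteroendocrine cells and 0.329 for fibroblast, endothelial and immune cells, both with hemin.

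On 2 arrays a single spot stood far from the rest: DES, encoding desmin, had a log2 ratio of 6.51 on DMEM-Hemin replicate c and at most 0.09 elsewhere, and CNR2 had 3.52 on DMEM-FBS replicate c and at most 0.31 elsewhere.

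DMEM-FBS replicate a lay near the SF-0 arrays. On the axis from DMEM-FBS replicates b and c (0) to SF-0 (1), built without the array in question, it stood at 0.536. The SF-0 arrays stood at 0.621, 0.682 and 0.784, each on an axis from the remaining SF-0 arrays, so the scales may differ. Replicates b and c have no such position. In a simpler version, whose origin and direction share arrays, they stood at 0.432 and 0.335, replicate a at 0.648 and the SF-0 arrays at 0.70 to 0.836. Left-out arrays thus do not reach 0 or 1. An exchange of labels with an SF-0 array needs a partner on the serum side, and the lowest SF-0 position, 0.621, argues against it. Random noise of that array is argued against by a correlation of 0.388 across genes between its deviation from replicate b and the difference of SF-0 from replicate c, which share no array. Features with large differences were chosen without that array and without SF-0 replicate a, b or c in turn. On them it lay nearer to DMEM-FBS replicates b and c in 34.7%, 31% and 27.3%. The SF-0 array left out did so in 13.3%, 11.9% and 28.6%, so the shares overlap only through SF-0 replicate c. The position of 0.536 lies below the SF-0 range by less than the spread within it. A wrong label without a partner thus cannot be told apart from a serum sample in another state, and no biological explanation was tested.

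Metallothionein genes were called higher with hemin (8 of 8) and, for 4 of 8, with FAC. MT1B, MT1F, MT1M and MT2A also lay higher with FAC, by 0.58 to 0.70 (log2), without passing (limma adjusted p 0.0557 to 0.109). Scaling between arrays is argued against, since the list's camera adjusted p under quantile normalization was at most 1.68e-07. The run without centring is no test of it, since the deposited values were already centred. Cross-hybridisation of 1 transcript to all metallothionein probes stays open: the lowest correlation with MT2A over the 12 arrays, that of MT1F, was 0.728, between the bounds of 0.9 and 0.5 set for it. A hypothesis of a metal response that also raises the zinc exporter SLC30A1, a target of the same metal-responsive transcription factor, by 0.3 (log2) or more is argued against by its 95% confidence intervals, which end at 0.09 for hemin and 0.26 for FAC. That bound was set after the values were seen and rests on 1 gene, so a response of metallothioneins alone, or a weaker one of SLC30A1, may still apply.

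The hypoxia response list lay lower with hemin and with FAC. With hemin its median log2 difference was -0.168 with all arrays and -0.095 without DMEM-FBS replicate a. Scaling between arrays is argued against, since the camera adjusted p under quantile normalization was at most 1.36e-05 in both comparisons. Here too the run without centring is no test, since the deposited values were already centred. Members that vary together between replicates stay open: with an estimated correlation the lower of both adjusted p was 0.164, while fry gave 0.0444 for hemin and 0.0122 for FAC. One hypothesis is that iron, a cofactor of the prolyl hydroxylases that mark HIF for destruction, may lower HIF targets as one response to either source. The effects of the 34 members correlated at r = 0.244 between the comparisons (rho 0.132, permutation p = 0.16), against a 95th percentile of 0.478 in 10000 random lists, which neither bears this out nor excludes it.

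For the pairwise comparisons, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real hemin split gave 344 features and the highest of the others 0, and the real FAC split 16 against 2. SF-FAC against DMEM-FBS gave 18 against 1. For withdrawal the real split gave 2 features and another gave 3, so that 2 of the 10 splits gave as many. In the other 3 comparisons, 1 of the 10 splits, the real one, gave as many.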
